A study of Mus musculus with 18 samples.

How the data were processed

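RNA from mouse testis was hybridised to 18 Agilent one-colour (Cy3) mouse arrays, in 6 groups of 3: animals labelled wild type and animals labelled Plin1 knockout, each at days 21, 40 and 60 after birth. The labels call these ages the meiosis, puberty and mature phases. Per the labels, total RNA was taken up in TRIZOL, checked for integrity on an Agilent Bioanalyzer, purified on RNeasy columns with a DNase step, amplified and labelled with Cy3 using a Low Input Quick Amp kit. No label says whether each array is a separate animal, so the p-values of single probes measure the spread between these arrays. How the knockout allele was made, which part of the gene it removes, and the strain background are not given in the sources used here.

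The deposited files hold, for each array, 45018 spots quantified with Feature Extraction. Per the file headers the version was 10.7.3.1, whereas the submitters' processing notes name version 9.1, and the headers were followed. Per the file headers, the processed signal is a linear fluorescence intensity from which local background was subtracted and spatial trends were removed, with no scaling between arrays. The deposited series table holds the same intensity values, with a largest difference of 0 from the processed signal of the same spot, so an analysis of that table gives the same results.

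Of the spots on each array, 43379 were not controls, and they stood for 41174 probes, 245 of which were printed as 10 spots. Control spots and spots marked as outliers (72 to 137 per array) were left out, no spot was saturated, and spots of a probe were averaged on the log2 scale. A probe was tested if it was marked as well above background on all 3 arrays of at least 1 group, which left 35639 probes, 31124 of them well above background on all 18 arrays. Gene names came from matching the accession that the deposited files give for each probe to a RefSeq gene table. By this match 25058 tested probes carried a symbol. The 17075 genes were each represented by the probe with the highest mean log2 signal, which mattered for the 6116 genes with more than 1 tested probe. Of all 41174 probes, 14286 had no match in that table and so carried no symbol. Values are log2 signal minus the 75th percentile of the same array, so a value of 0 is as bright as that percentile. Where a gene was not well above background on any array of a group, the fold against that group is given as a lower bound, and elsewhere the number of arrays that measured it is given.

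Differences were tested with limma (lmFit and eBayes, two-sided) on the 6 group means over all 18 arrays, with Benjamini-Hochberg adjustment over the 35639 probes of each comparison and a threshold of 0.05 on the adjusted p. The comparisons were knockout-labelled against wild-type-labelled arrays at each age, their mean over the ages, the change of that difference with age (a moderated F test, called the interaction below), and the changes from day 21 to day 40 and from day 40 to day 60 within each label. Adjusted p-values of single genes are limma's throughout. Standard errors (SE) are those of the fitted difference, with the spread pooled over the 6 groups, and SD is the spread between the 3 arrays of a group.

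Gene lists were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 20 lists of a comparison. This test compares a list's genes with the other genes under that assumed correlation. Its p-value therefore does not measure how well a list's shift repeats between arrays. Beside it stand camera with an estimated correlation and limma's fry, which asks whether a list's genes move one way on balance and compares them with no other genes. The 20 lists held 387 distinct genes, of which 351 were measured: lipid droplet coat and lipolysis, steroidogenesis, Leydig cell markers, cholesterol biosynthesis and uptake, fatty acid synthesis, fatty acid oxidation and PPAR targets, adipocyte markers, Sertoli cell markers, spermatogonia markers, early meiosis, pachytene spermatocyte and meiotic division, round spermatid, elongating spermatid, peritubular and smooth muscle markers, macrophage and antigen presentation, endothelial markers, epididymis markers, red blood cell markers, interferon response, and immediate-early and stress genes. The number of members past the threshold is given over all probes and adjusted over the list alone. Genes next to Plin1, and genes within 10 Mb of it, were found in the RefSeq gene table of assembly GRCm38.p6, which differs from the array's annotation build, so no coordinates are given. A one-sided Fisher exact test compared them with the other genes, and its p-value counts genes, not arrays.

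The groups, comparisons, tests, gene lists, thresholds and most alternative settings were fixed before the data were examined, and so was the rule for naming genes. It takes Plin1 in every comparison of labels. The rule leaves out the intervals within knockout-labelled arrays. In each comparison of labels, the average included, and each interval within wild-type-labelled arrays, it takes the 10 genes with the highest and the 10 with the lowest log2 difference among those past the threshold whose 3 values in one group all lie on one side of the 3 in the other. For the average over ages the requirement is instead the same sign at all 3 ages. Where fewer than 5 genes pass in a direction, it takes the 5 with the smallest p in that direction, named as not past the threshold. From each list it takes up to 4 members with the smallest p, from the interaction the 5 genes with the smallest p, and in each comparison of labels a fixed set of steroidogenic, lipid droplet and germ cell genes, of which Insl3 and Sycp3 had no tested probe under their symbol. F5 and Clic6 fall outside the rule and were named after their values were seen.

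The alternatives were normexp background correction (offset 50) on the median spot signal, since the files hold no mean signal, quantile normalisation, scaling to the median in place of the 75th percentile, the series table, no filter, a filter requiring all 18 arrays, slide as a fixed or as a random block, replicate number as a block, a mean-variance trend with robust eBayes, array weights, a fit to the compared groups alone, thresholds that add a 2-fold change, the mean of a gene's probes, both other list tests, windows of 5 and 20 Mb, and leaving out each array. Per the file headers, the arrays lie on 5 slides. Alternatives chosen after seeing the data were a fit without both day 21 arrays that stand apart and a fit with 6 adipocyte transcripts as a covariate. Replicate numbers were checked for pairing before use. Other splits of the same arrays were counted for each comparison, all 10 for 3 arrays against 3, and 100 drawn with a fixed seed for the average over ages and the interaction.

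The procedure was tested on simulated data for the day 21 comparison of labels, with 35639 probes and 50 changed probes of each size. It called 22% of the probes changed by 0.5 on the log2 scale, 74% of those changed by 1, 82% of those changed by 2 and 94% of those changed by 3, with 4 false calls, 2.86% of all calls. For lists, over 17075 simulated genes, camera called the list moved by 0.5 and 0 of the other lists. The simulated noise was independent between genes, with the spread of each probe pooled over the 6 groups. In the real wild-type-labelled arrays the mean of the elongating spermatid list had an SD of 1.37 at day 21 and 0.03 at day 60. The estimated correlation within that list was 0.77. The simulated rates therefore do not cover the spread at day 21 or correlated lists. With 3 arrays in each group, the number of arrays limits the precision. The software was R 4.3.3 with limma 3.58.1, data.table (version 1.17.8), jsonlite 2.0.0 and statmod 1.5.0, and Python 3.11.15 with matplotlib 3.10.9 for the figures.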

Results

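Gene expression was measured in mouse testis with 18 one-colour arrays, 3 for each of 6 groups: arrays labelled wild type and arrays labelled Plin1 knockout at days 21, 40 and 60 after birth. Between 79.5% and 90.6% of the spots of an array were well above background, and the 75th percentile of the processed signal lay between 2245 and 3180. At day 21, 87.2 ± 2.14% of spots (SD, n = 3) were well above background in wild-type-labelled and 88.3 ± 2.87% in knockout-labelled arrays. The corresponding shares were 85.0 ± 1.34% and 84.8 ± 1.05% at day 40, and 82 ± 2.60% and 83.3 ± 0.386% at day 60. The first principal component, which carried 66.0% of the variance between arrays, ran from day 21 to the later ages. Within the groups of days 40 and 60, arrays correlated over probes at 0.992 or higher. The lowest correlation within a group at day 21 was 0.973 among wild-type-labelled and 0.967 among knockout-labelled arrays. Day 21 wild-type-labelled replicate 3 stood at -201.7 on the first component, against -122.4 and -126.0 for the other arrays of its group. Day 21 knockout-labelled replicate 2 stood at 153.2 on the second component and had the highest median signal of all arrays, 527, against a lowest of 274.

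Plin1, which encodes a coat protein of lipid droplets best known from fat cells, was read first as a check of the labels, and its probe was brighter in the arrays labelled knockout. At day 21 its log2 signal relative to the array's 75th percentile was -0.04 ± 0.06 (SD, n = 3) in knockout-labelled arrays and -1.76 ± 0.50 (n = 3) in wild-type-labelled arrays. At day 40 the values were -0.09 ± 0.13 and -2.42 ± 0.12, and at day 60 they were 0.0031 ± 0.14 and -2.75 ± 0.52. The lowest of the 9 knockout-labelled arrays, at -0.22, lay above the highest wild-type-labelled array, at -1.24. Plin1 was therefore higher by 1.72 (SE 0.24, limma adjusted p = 0.00278) at day 21, by 2.33 (SE 0.24, adjusted p = 0.00509) at day 40, and by 2.75 (SE 0.24, adjusted p = 0.000622) at day 60. A loss of the transcript under the probe would run the other way, so in every comparison of labels that follows, a direction is one between labels. The 6 genes nearest to Plin1 on either side, Rhcg, Ticrr, Kif7, Pex11a, Wdr93 and Mesp1, did not pass the test in any comparison of labels. Between arrays that share a slide, the differences in Plin1 were 1.78 at day 21 (1 knockout-labelled and 3 wild-type-labelled arrays), 2.23 at day 40 (3 and 1) and 2.92 at day 60 (1 and 3). With slide as a fixed block the adjusted p-values were 0.359, 0.330 and 0.0664. The average over ages, 2.31, kept an adjusted p of 0.0139. Over all alternatives the adjusted p-values ran from 0.000372 to 0.821 at day 21, from 3.91e-05 to 0.330 at day 40 and from 8.16e-06 to 0.952 at day 60. The difference ran from 1.48 to 3.05 over the 3 ages.

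**Figure D1:**
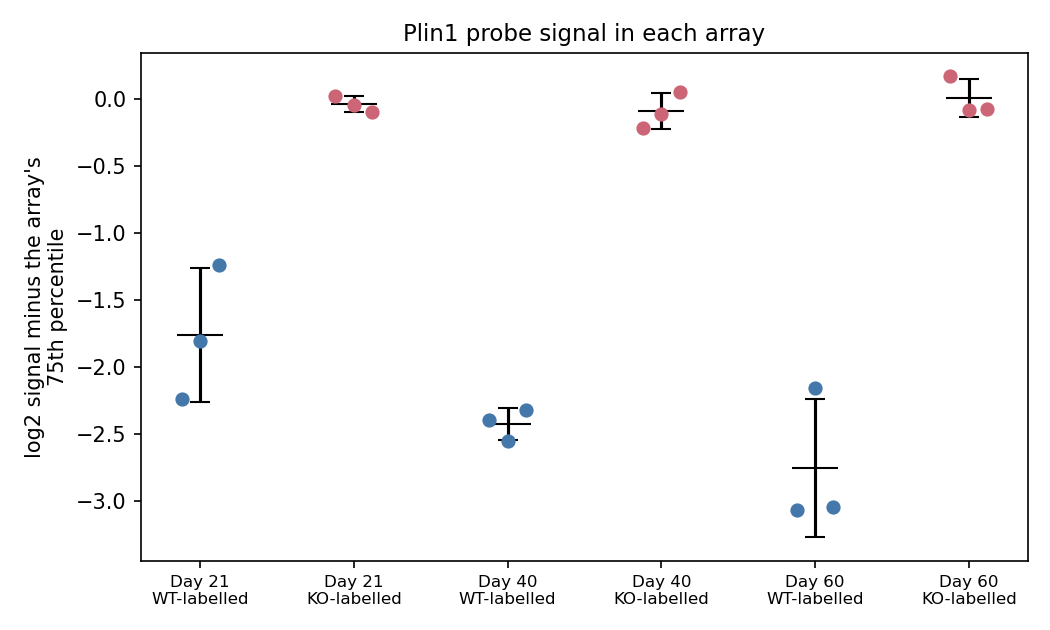
Signal of the Plin1 probe in each array, as log2 signal minus the array's 75th percentile. Points are arrays, horizontal bars are group means and error bars are SD (n = 3). The 9 knockout-labelled arrays lie at -0.22 or above and the 9 wild-type-labelled arrays at -1.24 or below.

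The comparison of labels at day 21, when the first wave of germ cells is passing through meiosis, asks how the labelled groups differ in the juvenile testis. Genes of late spermatids were higher in the arrays labelled knockout. Prm2, a protamine that packs sperm DNA, stood at 5.29 ± 0.98 (SD, n = 3) in knockout-labelled and 1.73 ± 1.93 in wild-type-labelled arrays, a difference of 3.56 (SE 0.68, adjusted p = 0.0163). Prm1, the other protamine, was higher by 3.37 (adjusted p = 0.0183). Tnp2, a transition protein that replaces histones before the protamines, was higher by 2.84 (adjusted p = 0.0141), and Fscn3, a testis fascin that bundles actin, by 2.71 (SE 0.37, adjusted p = 0.00225). The SE and adjusted p of these genes pool the spread over all 6 groups. A limma fit to the day 21 arrays alone called 0 probes, with 1376 at an unadjusted p under 0.05. Of 24 measured elongating spermatid genes, 6 rose over all probes and 16 rose adjusted over the list alone. A difference above 0 was found in 23, and the median difference was 1.41 (camera adjusted p = 1.38e-13, adjusted p = 0.977 with an estimated correlation). Tnp1 differed by 2.58 without passing (adjusted p = 0.0534). Of 27 round spermatid genes, 0 passed limma's test either way, at a median difference of 1.17 with 24 above 0 (camera adjusted p = 5.56e-06, adjusted p = 0.977 with an estimated correlation). Examples are Fhl5, a testis LIM-domain protein (1.81, adjusted p = 0.163), and Actl7a, an actin-like protein of the acrosome (1.38, adjusted p = 0.235). These lists moved with the array that stood apart: the mean of the elongating spermatid genes was -0.39 in wild-type-labelled replicate 3, 2.02 and 1.93 in the other wild-type-labelled arrays, and 3.03, 2.31 and 3.23 in the knockout-labelled arrays. Without that replicate the median differences were 0.51 for elongating and 0.18 for round spermatid genes, and the camera call of the round spermatid list ended. With slide as a fixed block the median differences were 1.55 and 1.24. That block compares knockout-labelled replicate 1 alone with the 3 wild-type-labelled arrays, replicate 3 included, so it is no check on that replicate.

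**Figure D2:**
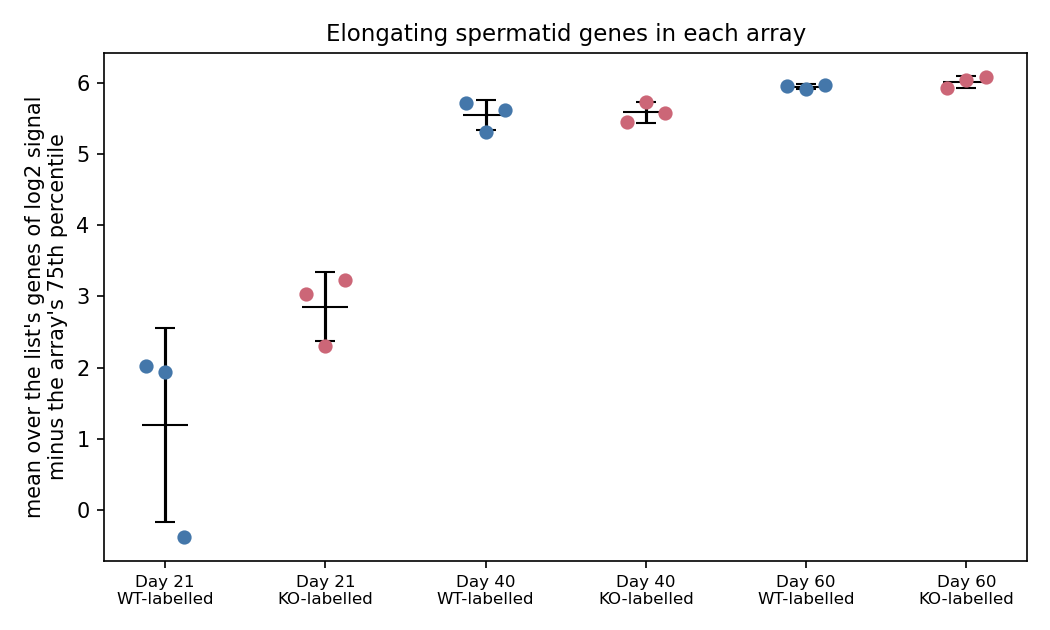
Mean over the measured elongating spermatid genes of the log2 signal minus the array's 75th percentile, per array. Points are arrays, horizontal bars are group means and error bars are SD (n = 3). At day 21 wild-type-labelled replicate 3 lies at -0.39, below every other array.

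Across all probes at day 21, 481 were higher and 7 lower in the arrays labelled knockout. They held 256 genes higher and 1 lower, 164 probes without a symbol, and 433 probes changed at least 2-fold. The largest rises were in Bpifa3 (4.14, SE 0.65, adjusted p = 0.00549), Abra (4.02, adjusted p = 0.00597), 1700016C15Rik (3.96, adjusted p = 0.0140) and Hemgn (3.90, adjusted p = 0.00434). Bpifa3 was well above background on 2 and Abra on 1 of the 3 wild-type-labelled arrays. Nudt16l2 (3.67), Ttc24 (3.65), 1700009J07Rik (3.63), Zic5, a zinc finger transcription factor (3.61), and Mtnr1a, a melatonin receptor (3.58), rose as well. Zic5 was measured on 2 and Mtnr1a on 1 of the 3 wild-type-labelled arrays. The gene that fell was Rbbp8, which trims broken DNA ends for repair by recombination, at 1.90 ± 0.06 against 2.27 ± 0.07 (SD, n = 3), a difference of -0.37 (SE 0.08, adjusted p = 0.0259). Med11, a Mediator subunit (-0.37, adjusted p = 0.0509), Sdhaf1, an assembly factor of succinate dehydrogenase (-0.40, adjusted p = 0.0526), Magea3 (-0.43) and Rab7b (-0.70) did not pass. The count was 365 without wild-type-labelled replicate 3, 440 without knockout-labelled replicate 2, 582 without both and 1031 without wild-type-labelled replicate 2. With slide as a fixed block, which compares 1 knockout-labelled with 3 wild-type-labelled arrays of a slide, 2 probes passed. A random slide block gave 2933 (2232 higher and 701 lower) and normexp correction 122. Without knockout-labelled replicate 1, 704 were higher and 256 lower, and without wild-type-labelled replicate 2, 936 and 95, so the small number of lower calls depended on the arrays. A limma fit to the day 21 arrays alone called 0 probes, with 1376 at an unadjusted p under 0.05, so the calls rest on pooling the spread with the later ages.

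Lipid and steroid genes at day 21 held few calls. Cyp51, the lanosterol demethylase of cholesterol synthesis, rose by 1.09 (SE 0.19, adjusted p = 0.0108), from -1.83 ± 0.25 in wild-type-labelled to -0.75 ± 0.32 in knockout-labelled arrays (SD, n = 3), as the single call among 24 genes of cholesterol biosynthesis and uptake (camera adjusted p = 0.842). Of the lipid droplet list 0 of 21 genes passed limma's test, with 0 adjusted over the list alone and 5547 probes at an unadjusted p under 0.05 in the whole comparison. Its members Plin2, the droplet coat protein found in most tissues (0.48, adjusted p = 0.154), Lipe, hormone-sensitive lipase (0.12, adjusted p = 0.676), and Pnpla2, the first lipase of triglyceride breakdown (-0.17, adjusted p = 0.374), did not pass. Among steroidogenic genes, Star, which brings cholesterol into mitochondria, differed by -0.11 (adjusted p = 0.882), Cyp11a1, which makes pregnenolone, by 0.67 (adjusted p = 0.273), and Cyp17a1 by 0.75 (adjusted p = 0.277). Hsd3b6 differed by 0.36, Hsd17b3 by 0.19 and the luteinising hormone receptor gene Lhcgr by 0.35. Calr3, a chaperone of meiotic and later germ cells, rose by 1.93 (adjusted p = 0.0221) as the single call among 19 pachytene genes (camera adjusted p = 0.925). Median differences of the lists without a call were 0.25 for Leydig cell markers (camera adjusted p = 0.106), -0.10 for Sertoli cell markers (0.106), -0.19 for immediate-early genes (0.0811), -0.50 for adipocyte markers (0.525) and -0.09 for early meiosis (0.525). Mean and median differed in sign for the lists of lipid droplets, cholesterol and red blood cells, and the test ran against the mean and median for macrophage genes.

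At day 40, the age the labels call puberty, Plin1 was the one gene that passed, and 1 of 35639 probes was called in the arrays labelled knockout against those labelled wild type. Sertoli cell genes, from the cells that nurse the germ cells, lay slightly higher in knockout-labelled arrays. In all, 19 of 23 were above 0 at a median difference of 0.20 (camera adjusted p = 0.000798, adjusted p = 0.861 with an estimated correlation). None of them passed limma's test over all probes and 3 rose adjusted over the list alone. Examples are Cst12, a cystatin (0.43, SE 0.11, adjusted p = 0.241), Fshr, the receptor of follicle-stimulating hormone (0.38), Dhh, a hedgehog ligand (0.37), and Inhbb, an inhibin and activin subunit (0.34). Peritubular and smooth muscle genes had a median difference of 0.24 over 12 genes (camera adjusted p = 0.0280, adjusted p = 0.861 with an estimated correlation), with 1 risen adjusted over the list alone. Among them were Tpm2, a tropomyosin (0.56, adjusted p = 0.229), and Myl9, a myosin light chain (0.28). Interferon response genes were all 16 below 0, at a median of -0.48 (camera adjusted p = 0.000376, adjusted p = 0.861 with an estimated correlation). Examples are Ifit1 (-1.08, SE 0.46, adjusted p = 0.473) and Irf7 (-0.81). Their mean was -2.52 in wild-type-labelled replicate 3, against -4.04 and -4.09 in the other wild-type-labelled arrays and -4.13 to -3.92 in the knockout-labelled arrays. Without replicate 3 the median difference was 0.08. The peritubular call ended without that replicate (0.19), and also without knockout-labelled replicate 1 (0.20) or replicate 2 (0.21). With slide as a fixed block, which sets wild-type-labelled replicate 3 against the 3 knockout-labelled arrays, the median differences were 0.14 for Sertoli, 0.30 for peritubular and -1.56 for interferon response genes. It called 3 probes. The count depended on the model, at 388 with a random slide block, 2892 with array weights (1671 up and 1221 down) and 42 in a fit to the day 40 arrays alone.

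Steroid and lipid genes at day 40 did not pass over all probes. Hsd17b3, the enzyme of the last step to testosterone, was at -1.10 ± 0.71 in knockout-labelled and 0.35 ± 0.24 in wild-type-labelled arrays (SD, n = 3), a difference of -1.45 (adjusted p = 0.273), and Hsd17b1 differed by -1.05 (adjusted p = 0.185). Both the steroidogenesis list (median -0.02, camera adjusted p = 0.300) and the Leydig cell list (median -0.02, camera adjusted p = 0.271) had 2 genes fallen adjusted over the list alone. Star (0.37), Cyp11a1 (-0.02), Cyp17a1 (-0.13), Plin2 (0.04), Lipe (-0.09) and Pnpla2 (-0.20) did not pass, nor did Prm1 (0.02) and Tnp1 (0.26). The genes nearest to the threshold beyond Plin1 were Meak7 (-1.25, adjusted p = 0.118), Ska3, a kinetochore component (-1.53, adjusted p = 0.126), Syne1, a nuclear envelope spectrin-repeat protein (0.57, adjusted p = 0.126), 2210016L21Rik (0.52) and Tmed9, a cargo receptor of the early secretory pathway (-0.62, adjusted p = 0.133). Hip1r (-0.60), Rrp8 (-0.74), Rbmx (0.42), Rmrp (1.17) and Sema6d (0.58) followed. The single call ended without wild-type-labelled replicate 2 or knockout-labelled replicate 3, when Plin1 differed by 2.26 each time and 0 probes passed. A total of 3448 probes had an unadjusted p under 0.05, against 1782 that chance alone would give.

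At day 60, in the mature testis, Plin1 was again the 1 called probe in the comparison of labels, and 2120 probes had an unadjusted p under 0.05. Adipocyte genes lay higher in the arrays labelled knockout, with 17 of 19 above 0 at a median difference of 0.34 and a mean of 1.06 (camera adjusted p = 0.00513, adjusted p = 0.793 with an estimated correlation). Of them 0 passed limma's test over all probes or adjusted over the list alone. Retn, the fat-cell hormone resistin, differed by 1.89 (SE 1.09, adjusted p = 0.875), and Pparg, the master regulator of fat-cell formation, by 0.34 (adjusted p = 0.806). The list's mean was 0.04 in knockout-labelled replicate 2, against -2.12 and -3.04 in the other knockout-labelled and -2.24, -3.01 and -3.07 in the wild-type-labelled arrays. Without that array the median difference was 0.0075. The call also ended without wild-type-labelled replicate 2 (0.32), and with slide as a fixed block the median difference was 0.13. Genes with the smallest p beyond Plin1 were Eif4e3, a cap-binding translation factor (0.98, adjusted p = 0.806), Map3k14 (0.35) and Map3k15 (0.42), both signalling kinases, and Magea1 (0.46). On the lower side they were Adgre1, a macrophage surface receptor (-0.50), Serhl (-0.55), Dab2ip (-0.42), Mef2c, a transcription factor of muscle and vessels (-0.62), and Klhl42 (-0.95), at the same adjusted p. Scd4, also picked by its p, was not above background in either group. Star (-0.11), Cyp11a1 (-0.20), Cyp17a1 (-0.31), Hsd3b6 (-0.33), Hsd17b3 (-0.32), Lhcgr (-0.38), Plin2 (-0.21), Lipe (0.06), Pnpla2 (0.07), Tnp1 (0.13) and Prm1 (-0.03) did not pass. The median differences of the lipid droplet (0.07, camera adjusted p = 0.466), steroidogenesis (-0.02, adjusted p = 0.932), Leydig cell (-0.12, adjusted p = 0.401) and endothelial (0.12, adjusted p = 0.0633) lists did not pass either.

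Averaged over the ages, 6 probes were higher in the arrays labelled knockout and 0 lower, while 3096 had an unadjusted p under 0.05 in limma's test. Plin1 was higher by 2.27 (SE 0.14, adjusted p = 6.16e-06). The transcripts 1700008P02Rik (1.05, SE 0.14, adjusted p = 0.0218) and 4930412O13Rik (0.95, SE 0.11, adjusted p = 0.00843) also rose. F5, which encodes coagulation factor V and was named after its values were seen, rose by 0.79 (adjusted p = 0.0170) with a difference of -0.01 at day 40. The other 2 probes carry no symbol. Elongating spermatid genes had a median difference of 0.51 (camera adjusted p = 8.15e-08, adjusted p = 0.988 with an estimated correlation), with 0 risen over all probes and 2 risen adjusted over the list alone. This came from day 21, since the list's median difference was 0.02 at day 40 with 14 of 24 above 0 (camera adjusted p = 0.667) and -0.0035 at day 60 with 11 above 0 (adjusted p = 0.854). Without day 21 wild-type-labelled replicate 3 the averaged median of the elongating spermatid list was 0.21, and over all alternatives it ran from 0.21 to 0.72. Its smallest p-values were those of Fscn3 (0.98, adjusted p = 0.144) and Tnp2 (1.16, adjusted p = 0.234). Early meiosis genes had a median of -0.06 (camera adjusted p = 0.0206, adjusted p = 0.573 with an estimated correlation), as in Dmc1, a recombinase of meiosis (-0.21, adjusted p = 0.464). Srgap1 (0.69, adjusted p = 0.0540), Padi6 (0.69), B4galnt4 (0.77), Kcnip2 (0.89) and Gad2 (0.81) did not pass, nor did Rrp8 (-0.48, adjusted p = 0.0987), Tmed9 (-0.38), Meak7 (-0.61), Zfp91 (-0.35) and Ehbp1 (-0.38). The number of calls was 152 without day 21 wild-type-labelled replicate 2, 3 without day 40 wild-type-labelled replicate 2, and 1, Plin1, with slide as a fixed block. Lower probes were called too without day 21 knockout-labelled replicate 1 (33 higher and 40 lower), with a random slide block (79 and 33) and with array weights (339 and 47). The fixed block gave median differences of 0.50 for elongating spermatid and -0.05 for early meiosis genes.

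The interaction test, which asks whether the difference between labels changes with age, called 9 probes, with 4667 at an unadjusted p under 0.05. The named genes among them were 4930412O13Rik, 1700008P02Rik and Klk1b26, a kallikrein, each higher in knockout-labelled arrays at day 21 and not past the test at days 40 and 60. Nudt16l2 and 1700009J07Rik followed without passing (adjusted p = 0.0545 for each). With slide as a fixed block 0 probes passed limma's interaction test, and leaving out single arrays gave from 2 calls (without day 21 wild-type-labelled replicate 1) to 317 (without day 21 wild-type-labelled replicate 2).

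From day 21 to day 40 in the arrays labelled wild type, the interval over which spermatids first complete their development, spermatid genes rose steeply. Of 24 elongating spermatid genes 23 rose over all probes, and 23 adjusted over the list alone, at a median of 4.51 (camera adjusted p = 1.44e-15, adjusted p = 0.738 with an estimated correlation). Fscn3 went from -2.88 ± 0.84 to 4.50 ± 0.23 (SD, n = 3), a rise of 7.38 (SE 0.37, adjusted p = 4.39e-09), Spem1, needed to shape the sperm head and neck, rose by 7.35, Tnp2 by 7.28 and Tssk6, a testis-specific kinase, by 5.18. Of 27 round spermatid genes 22 rose, at a median of 2.56 (camera adjusted p = 6.55e-09, adjusted p = 0.799 with an estimated correlation), among them Fhl5 (4.55), Tssk2 (3.49) and Actl7a (3.27). Without day 21 wild-type-labelled replicate 3 the medians were 3.49 for the elongating spermatid list and 1.64 for the round spermatid list. Leydig cell genes rose in 10 of 17 cases and fell in 2 (3 adjusted over the list alone), at a median of 1.22 (camera adjusted p = 0.000138, adjusted p = 0.738 with an estimated correlation). Cyp17a1, which makes androgens from progestins, rose by 3.94 (SE 0.32), Hsd17b3 by 3.71, Ptgds, a prostaglandin D synthase, by 3.0 and Ephx1 by 2.19. Sertoli cell genes fell in 17 of 23 cases, at a median of -0.63 (camera adjusted p = 0.0274, adjusted p = 0.962 with an estimated correlation). Amh, the anti-Müllerian hormone of immature Sertoli cells (-1.62, SE 0.14), Fshr (-1.17), Dhh (-0.91) and Cst12 (-0.84) were among them. The Sertoli call held under 16 of 22 alternatives, with medians from -0.73 to -0.49, and ended without day 21 wild-type-labelled replicate 3 or day 40 wild-type-labelled replicate 1. No slide held arrays of both day 21 and a later age, so slide and age cannot be told apart in this comparison.

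**Figure D3:**
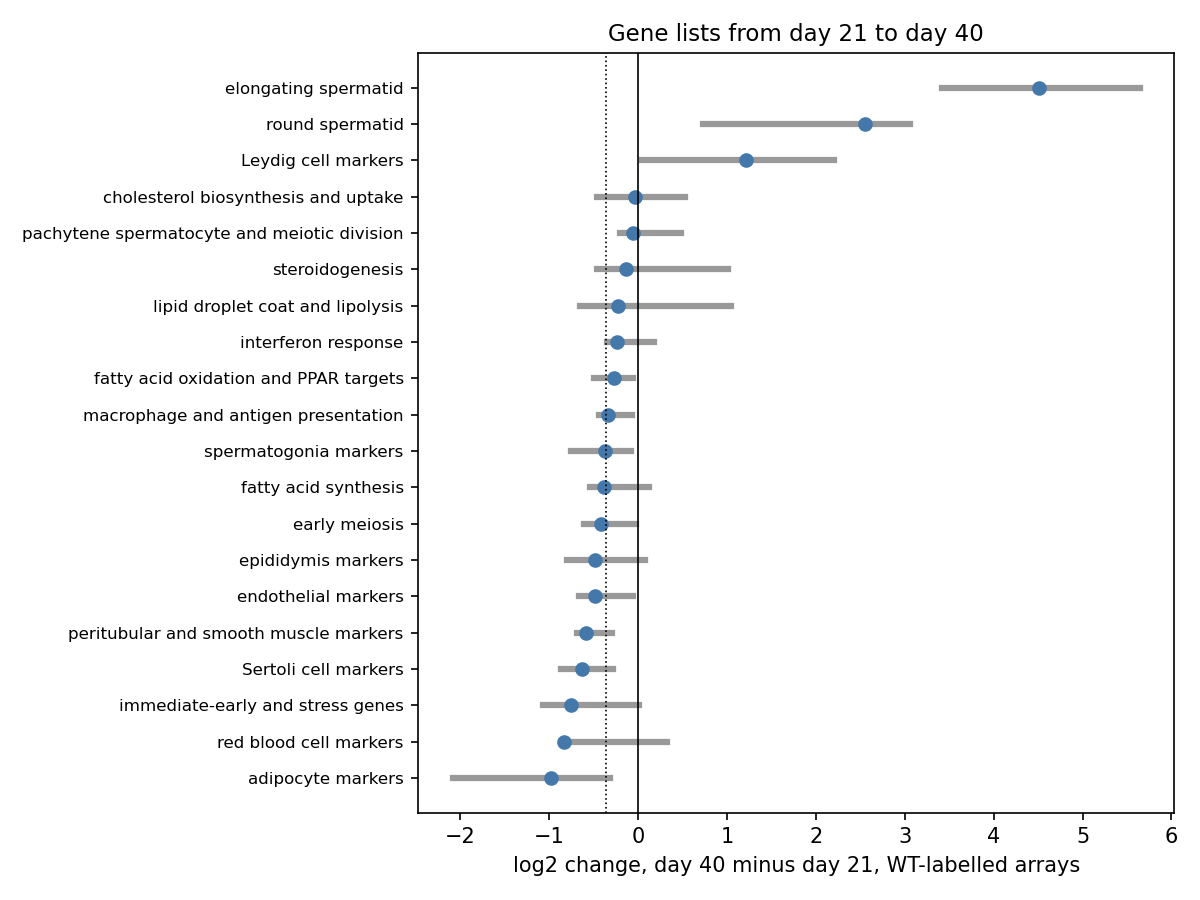
Change of each gene list from day 21 to day 40 in wild-type-labelled arrays, in log2 units. Dots are the median over a list's measured genes, bars span the middle of the list from the first to the third quartile, the solid line marks no change and the dotted line the median over all probes, -0.36. Elongating spermatid genes have the highest median, 4.51, and Leydig cell genes a median of 1.22.

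Genes of lipid and steroid handling moved both ways from day 21 to day 40 in wild-type-labelled arrays. Of 19 steroidogenesis genes 7 rose and 7 fell (median -0.14, mean 0.47, camera adjusted p = 0.224), as in Cyp11a1 (2.20) and Srd5a1, the testosterone 5-alpha-reductase (-1.12). Of 21 lipid droplet genes 7 rose and 6 fell (median -0.22, mean 0.15, camera adjusted p = 0.195), with rises in Dgat2, an enzyme of triglyceride synthesis (3.0), Lipe (2.30), Abhd5, a co-activator of triglyceride lipase (2.03), and Plin2 (1.05). Of 24 cholesterol genes 8 rose and 7 fell (median -0.03, mean 0.29, camera adjusted p = 0.195), including Insig1, a brake on sterol synthesis (3.69), and Cyp51 (3.36). The list of fatty acid synthesis had 3 genes up and 8 down of 19 (adjusted p = 0.929), with Agpat2 up by 4.47, and fatty acid oxidation 1 up and 9 down of 22 (adjusted p = 0.694). Of the adipocyte list 2 genes rose and 6 fell of 19 (adjusted p = 0.929), the risen ones being Acsl1, an acyl-CoA synthetase (3.82), and Lipe, with camera against the sign of median and mean.

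Germ cell lists of earlier stages and the other cell types over the same interval gave no camera call. Spermatogonial genes fell in 9 of 15 cases and rose in 1 (adjusted p = 0.694), as in Sohlh2 (-0.93) and Dmrt1 (-0.76), both transcription factors of early germ cells. Early meiosis genes fell in 11 of 19 cases and rose in 4 (adjusted p = 0.745), with Dmc1 at -0.85 and Syce2, a part of the synaptonemal complex, at 1.65. Pachytene genes rose in 6 and fell in 3 of 19 cases (median -0.06, mean 0.38, adjusted p = 0.197), Calr3 by 4.99. Peritubular genes fell in 6 and rose in 1 of 12 cases (adjusted p = 0.527), endothelial genes fell in 5 and rose in 2 of 13 (adjusted p = 0.929). Immediate-early genes fell in 12 and rose in 3 of 19 (adjusted p = 0.527), with Egr2 at -1.66, Egr1 at -1.30 and Socs3 at -1.28. Macrophage genes fell in 2 and rose in 1 of 18 (adjusted p = 0.929), the risen one being Aif1 (3.74). Epididymis genes fell in 3 and rose in 2 of 10 (adjusted p = 0.929), with Cst8, a cystatin also made in the testis, up by 4.33. Of 16 interferon response genes 2 fell over all probes and 1 adjusted over the list alone (adjusted p = 0.745), and of 5 red blood cell genes 1 fell (adjusted p = 0.929).

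Over all probes, 20905 of 35639 (58.7%) passed from day 21 to day 40 in wild-type-labelled arrays, 5731 up and 15174 down, among them 3127 genes up and 7582 down. The rises were led by Nudt16l2 (9.02, SE 0.42), Bpifa3 (8.83), 1700009J07Rik (8.79), Ttc24 (8.65), Oxct2a, a testis enzyme of ketone use (8.54), Cstl1 (8.51), Abra (8.50), 1700016C15Rik (8.38), Prkar2a, a regulatory subunit of protein kinase A (8.12), and Hemgn (7.97). At day 21 Bpifa3 was measured on 2 and Abra on 1 of these 3 arrays, so their sizes are uncertain. Large falls included the globin genes Hba-a1 (-4.40, SE 0.53) and Hbb-bt (-4.23), Stc1, a stanniocalcin hormone (-3.20), Ahsg (-3.17) and 4930486L24Rik (-3.0). Olfr1463, Gjb6 and Apoc3 were not well above background at day 40 and fell at least 3.98-fold, 4.93-fold and 1.99-fold, but with normexp correction their changes were upward (0.43, 0.47 and 0.68), and Olfr1221 (-2.99) was measured on 1 of 3 arrays at day 40. The median over all probes was -0.36, and its sign turned with normexp correction (0.18). The share of calls that were higher, 27.4%, was 33.0% with median scaling and 46.3% with normexp correction. The calls numbered 7297 with normexp correction, under which the lists of Sertoli and Leydig cells kept the direction of their medians.

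From day 40 to day 60 in wild-type-labelled arrays, 0 probes passed limma's test, with 4184 at an unadjusted p under 0.05. All 24 elongating spermatid genes lay higher at day 60, at a median of 0.45 (camera adjusted p = 0.00857, adjusted p = 0.992 with an estimated correlation), as in Tssk6 (0.62, SE 0.23, adjusted p = 0.343), Fscn3 (0.78) and Odf2, a protein of the outer dense fibres of the sperm tail (0.30). This call held under 18 of 22 alternatives, with medians from 0.17 to 0.55, and for the elongating spermatid list it ended with quantile normalisation (0.17) and normexp correction (0.31). Adipocyte genes had a median of -0.48 (camera adjusted p = 0.0482) and interferon response genes one of -0.51 (camera adjusted p = 0.00857), both with an adjusted p = 0.992 with an estimated correlation, and none of these members passed adjusted over the list alone. The adipocyte call held under 11 of 22 alternatives, with medians from -0.75 to 0.11. The interferon value moved with day 40 wild-type-labelled replicate 3, without which its median was 0.02. Cdkn1c, a cell cycle inhibitor (0.79, adjusted p = 0.129), Gsdmd, a pore-forming protein of cell death (0.95, adjusted p = 0.114), Faxc (1.01), Ubxn6 (0.50), Aars2 (0.53), Tmed9 (-0.66), Cldn12, a tight junction claudin (-1.60), Rrp8 (-0.77), Olfr1153 (-1.09) and Maml2 (-0.63) had the smallest p-values and did not pass. No slide held wild-type-labelled arrays of both ages. With slide as a fixed block 1 probe passed, and the median of the adipocyte list was 0.10 and that of the interferon list 0.07.

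In the arrays labelled knockout, 17617 probes passed from day 21 to day 40, 4258 up and 13359 down, among them 2503 genes up and 5767 down. Of 24 elongating spermatid genes 23 rose, at a median of 2.75 (camera adjusted p = 1.33e-14, adjusted p = 0.712 with an estimated correlation). Of 27 round spermatid genes 13 rose, at a median of 1.37 (camera adjusted p = 2.22e-06, adjusted p = 0.861 with an estimated correlation), and of 17 Leydig cell genes 9 rose and 3 fell, at a median of 0.90 (camera adjusted p = 0.000335, adjusted p = 0.712 with an estimated correlation). The share of calls that were higher was 24.2%, 44.4% with median scaling (5094 up and 6382 down) and 75.3% with normexp correction, so the mix of directions among the calls depended on the scaling and turned with the background method, while the median over all probes was -0.30, and -0.49 with normexp correction. From day 40 to day 60, 1 probe passed, for Clic6, a chloride channel family member named after its values were seen (1.38, SE 0.17, adjusted p = 0.0315), with 5663 at an unadjusted p under 0.05. A random slide block called 7833 probes and array weights 4703, while median scaling, no filter on dim probes and a fixed slide block called 0 by limma (5116, 5616 and 1198 at an unadjusted p under 0.05). No slide held knockout-labelled arrays of both day 40 and day 60. All 24 elongating spermatid genes were above 0 at a median of 0.47 (camera adjusted p = 0.00395, adjusted p = 0.875 with an estimated correlation), with 0 passing limma's test on their own. With normexp correction that median was 0.12, under the 0.71 of all probes, and the call ended. No camera call in any of the comparisons held with an estimated correlation.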

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

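The tests of exchanged labels, of the slide, of the day 21 wild-type-labelled array that stands apart, of the background of day 21 knockout-labelled replicate 2, of carried-over fat and of genotype as the source of the fat-cell genes were chosen after the results were seen. The difference between labels changed with age for 9 probes by the interaction test. The adjusted interaction p was 0.00575 for 4930412O13Rik, whose difference was 2.57 at day 21, 0.09 at day 40 and 0.19 at day 60. It was 0.0202 for 1700008P02Rik, with differences of 2.73, 0.29 and 0.15, and 0.0355 for Klk1b26, with differences of 2.17, -0.12 and 0.10. Klk1b26 belongs to a kallikrein family of close copies, and its single probe was not checked against the other copies. Groups of 3 arrays are too small for the rule that looks for single outlying samples.

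Plin1 was higher in all 9 arrays labelled knockout, by 2.27 (SE 0.14) averaged over ages. A slide effect is argued against, since the smallest difference within a slide was 1.78. Exchanged genotype labels stay open by the test set for them: Cidec is a fat-cell gene, and the slope of Plin1 on it within ages was 0.161 in wild-type-labelled arrays (exact p = 0.0463 over 216 permutations) and -0.0189 in knockout-labelled arrays (exact p = 0.657), a difference of -0.180 (95% interval -0.351 to -0.00855) that became -0.159 (-0.351 to 0.0341) without day 60 knockout-labelled replicate 2. Over all 6 fat-cell genes tried, the exact p in wild-type-labelled arrays ran from 0.0463 to 0.139 and the slopes in knockout-labelled arrays were below 0. These genes rise and fall together across arrays, so they are not separate tests. Without day 60 knockout-labelled replicate 2 the knockout-labelled slope on Cidec was 0.00227. Plin1 in knockout-labelled arrays ran from -0.22 to 0.17 while Cidec ran from 4.12% to 328% (that replicate) of the 75th percentile. This leans against exchanged labels, since fat with an intact Plin1 would raise it. A probe outside the deleted part of the allele, on a transcript that the targeted locus still makes, stays open too, since there is 1 probe for Plin1 and no description of the allele, and with exchanged labels every direction between labels would turn round.

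Spermatid genes were higher at day 21 in the arrays labelled knockout, at a median of 1.41 for the elongating spermatid list. The low values of wild-type-labelled replicate 3 may account for much of it but are argued against as the whole, since the median without that array was 0.508, but the round spermatid list then fell from 1.17 to 0.180 and lost its call, so for that list the array may account for the difference. A raised background of knockout-labelled replicate 2 is argued against, since the median without it was 1.66. A slide effect stays open, since only knockout-labelled replicate 1 shares a slide with the wild-type-labelled arrays of day 21. Testes further along the first wave of spermatogenesis, whether through genotype or through age or litter, stay open: the correlation over genes of the day 21 difference with the change from day 21 to day 40 in knockout-labelled arrays was 0.386 with all arrays but 0.182 without wild-type-labelled replicate 3 (Spearman 0.00227) and 0.518 (Spearman 0.229) without knockout-labelled replicate 2 as well, and genes are not independent replicates. Those comparisons share the day 21 knockout-labelled arrays, for which unchanged groups gave a simulated correlation of -0.500 (covariance -0.0422, against 0.168 observed with all arrays). The simulation held no change with age and a spread pooled over the 6 groups, so it misses the wider spread at day 21. It shows that sharing arrays pushes the correlation below 0, and gives no baseline for 0.386. Of the 481 probes higher at day 21, 414 rose in knockout-labelled arrays by day 40, against 57.5 if the calls were independent. The 481 calls include wild-type-labelled replicate 3, and 461 of them also rose in wild-type-labelled arrays by day 40. Low values in that replicate alone would favour such probes. The overlap was not counted without it, so it cannot tell the explanations apart.

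Fat-cell genes varied between arrays of a group, with Cfd low in 1 of the 6 day 21 arrays (knockout-labelled replicate 2, 9.34% of the 75th percentile against 264% to 631%) and the list high at day 60 in knockout-labelled replicate 2, where Fabp4 lay 6.67, Lpl 5.82, Cidec 5.56 and Adipoq 1.04 above the mean of the other day 60 arrays on the log2 scale. The difference between labels at day 60 rested on that array, since the median difference was 0.0075 without it. The array was picked as the richest in Cidec, itself on the list, and is labelled knockout. Leaving it out therefore had to shrink the difference, so genotype as the source is not settled by this value. Fat carried over with the testis stays open and cannot be told apart from other causes: 89.5% of the 19 measured adipocyte markers (17) were highest in that array among the 6 of day 60, but the array was picked by Cidec, itself one of them. Of these markers 17 were well above background on all 18 arrays and 4 stand on another list, and in the same array 76.9% of endothelial, 75% of peritubular and 61.9% of lipid droplet genes were the highest too.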

How the results depend on the processing

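The settings chosen after the data were seen were the fit without both day 21 arrays that stand apart and the fit with fat-cell transcripts as a covariate. The series table holds the same values as the processed signal, so it could not change a call, yet it is counted wherever alternatives are counted. Of the called values of named genes, all kept direction and call with the series table, a random slide block, a replicate block and a variance trend, 110 with median scaling, 105 with quantile normalisation, 109 with array weights and 75 with normexp correction, under which 33 lost the call and 4 reversed. Of the 22 for which a fixed slide block gives a value, 1 kept its call and 21 kept their direction alone. Of the 19 called list shifts, those in knockout-labelled development included, 18 kept their call with median scaling, 14 with quantile normalisation, 14 with normexp correction, 0 with an estimated correlation and 6 with fry. The cause was not tested for any value below unless named.

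The counts below are probes called by limma. With normexp correction they were 122 between labels at day 21, 0 at days 40 and 60, 1 for the average over ages, 0 for the interaction, 7297 from day 21 to day 40 in wild-type-labelled arrays, 2519 in knockout-labelled arrays and 0 from day 40 to day 60 there. Beside these 0 counts, 570 and 170 probes at days 40 and 60 and 7234 from day 40 to day 60 had an unadjusted p under 0.05. It moved the median difference of all probes between labels to 0.36, -0.22 and 0.18 at the 3 ages, and median scaling moved it to -0.12 at day 21. Over all alternatives the adjusted p of Plin1 ran from 0.000372 to 0.821 at day 21, from 3.91e-05 to 0.330 at day 40 and from 8.16e-06 to 0.952 at day 60. Under normexp Plin1 differed by 1.96 at day 40 (adjusted p = 0.178) and 1.67 at day 60 (0.952), the changes of Olfr1463 (0.43), Gjb6 (0.47), Apoc3 (0.68) and Lcn10 (0.27) from day 21 to day 40 in wild-type-labelled arrays reversed, and the interferon response list from day 40 to day 60 lost its call at a median of 0.40, beside 0.38 for all probes. In knockout-labelled arrays from day 40 to day 60, where the median of all probes under normexp was 0.71, the direction relative to the other genes turned for the elongating spermatid list (0.12), the round spermatid list (-0.19), the pachytene spermatocyte and meiotic division list (-0.25) and the epididymis markers list (2.02). Quantile normalisation gave 316 at day 21, 3 for the average and 15 from day 40 to day 60 in knockout-labelled arrays. Median scaling gave 11476 from day 21 to day 40 and 0 from day 40 to day 60 in those arrays, and 21 for the interaction. The stricter filter gave 9 for that last interval and 5 for the interaction, and no filter gave 0 for that interval (unadjusted p under 0.05 for 5616, and for 5116 with median scaling).

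Slide as a fixed block, which leaves fewer arrays to each difference, gave 2 at day 21, 3 at day 40, 1 for the average, 0 for the interaction, 1 from day 40 to day 60 in wild-type-labelled arrays and 0 in knockout-labelled arrays (unadjusted p under 0.05 for 1198). Plin1 was then 1.78 (adjusted p = 0.359), 2.23 (0.330) and 2.92 (0.0664), with an SE of 0.37 against 0.24, and from day 40 to day 60 the medians of the adipocyte markers list (0.10) and the interferon response list (0.071) reversed in wild-type-labelled arrays. No value can be had from day 21 to day 40. A random slide block, at an estimated correlation of -0.226 within slides, gave 2933, 388 and, rounded to 2 digits, 1.1e2 for days 21 and 40 and the average, 4776 for the interaction, and 3673 and 7833 from day 40 to day 60 in wild-type-labelled and knockout-labelled arrays. Replicate numbers did not pair the arrays, since 5 of 21 pairs with the same number correlated over 0.1, from -0.22 to 0.41, and the replicate block gave 14 for the average, 0 from day 40 to day 60 in knockout-labelled arrays (unadjusted p under 0.05 for 5385) and 14 for the interaction. Trend and robust eBayes gave 5 at day 40, 21 for the average, 1.1e2 for that interval and 54 for the interaction. Array weights gave 2892 at day 40, 386 for the average, 356 and 4703 from day 40 to day 60 in wild-type-labelled and knockout-labelled arrays, and 624 for the interaction.

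Fits to the compared groups alone gave 0, 42 and 0 at the 3 ages (unadjusted p under 0.05 for 1376 at day 21 and 4082 at day 60) and 4 from day 40 to day 60 in each label, with Plin1 at 1.72 (adjusted p = 0.821) at day 21 and 2.75 (0.245) at day 60. An added 2-fold change left 5683 and 4779 from day 21 to day 40 in wild-type-labelled and knockout-labelled arrays. An unadjusted p under 0.05 with a 2-fold change gave 2112, 240, 69 and 169 between labels and for the average, 5903 and 5320 from day 21 to day 40, and 227 and 331 from day 40 to day 60. Without both day 21 arrays that stand apart the average had 278 and the interaction 330. With fat-cell transcripts as a covariate the adipocyte markers list was at -0.049 between labels at day 60 and 0.083 from day 40 to day 60 in wild-type-labelled arrays. Called list shifts between labels, 8 in all, were 14 with a fixed slide block, 14 with array weights, 0 with an estimated correlation and 0 with fry. Those of wild-type-labelled development, 7 in all, were 4 with normexp, 4 with quantile normalisation, 0 with an estimated correlation and 13 with fry. The share of called genes near Plin1 stayed at 0 with windows of 5 and 20 Mb. With 3 called genes outside these windows and 185 tested genes inside the wider one, a share of 0 was nearly certain and decides nothing.

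Leaving out single arrays gave 365 (without wild-type-labelled replicate 3) to 1031 (without wild-type-labelled replicate 2) at day 21, also 822 without wild-type-labelled replicate 1 and 960 without knockout-labelled replicate 1. It gave 0 (without wild-type-labelled replicate 2 or knockout-labelled replicate 3) to 1 at day 40 and 1 to 2 (without wild-type-labelled replicate 3 or knockout-labelled replicate 1 or 3) at day 60. The average ran from 3, without day 40 wild-type-labelled replicate 2 or knockout-labelled replicate 1, day 60 wild-type-labelled replicate 1 or knockout-labelled replicate 2 or 3, to 152 without day 21 wild-type-labelled replicate 2, with 24 without replicate 3 of that group and 73, 59 and 11 without day 21 knockout-labelled replicates 1, 2 and 3. The interaction ran from 2 (without day 21 wild-type-labelled replicate 1, day 40 wild-type-labelled replicate 3 or knockout-labelled replicate 1 or 3) to 317 (without day 21 wild-type-labelled replicate 2). It was 45 without replicate 3 of that group, 91, 32 and 19 without day 21 knockout-labelled replicates 1, 2 and 3, 4 without replicate 1 of the wild-type-labelled arrays of day 40 or of day 60, and 5 without day 60 wild-type-labelled replicate 2. Intervals ran from 17520 to 20686 and from 12724 to 19144 from day 21 to day 40 in wild-type-labelled and knockout-labelled arrays, and from day 40 to day 60 from 0 to 3 (without day 60 wild-type-labelled replicate 3) in the former and from 0 (without any array of day 40 or replicate 2 of day 60) to 3 (without day 60 replicate 1) in the latter. Plin1 ran from 1.48 to 1.98, from 2.26 to 2.39 and from 2.60 to 3.05 at the 3 ages, at day 40 with an adjusted p of 0.0643 without wild-type-labelled replicate 2 and 0.0637 without knockout-labelled replicate 3. The interferon response list from day 40 to day 60 in wild-type-labelled arrays ran from -0.80 to 0.020, its sign turning without day 40 wild-type-labelled replicate 3, and called shifts of wild-type-labelled development ran from 6 to 8. Signal over background sets the depth: between 79.5% and 90.6% of spots were well above it, and genes under it could be given only as bounds.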

Other observations

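The test of linked alleles and the counts of other splits were chosen before the results were seen. In the arrays labelled knockout, genes of sterol handling moved in opposite directions from day 40 to day 60: of 24 measured genes of cholesterol biosynthesis and uptake 4 rose and 6 fell adjusted over the list alone, while 0 passed limma's test over all probes, where 5663 had an unadjusted p under 0.05, and the list's median was -0.14 (camera adjusted p = 0.229). Of 21 lipid droplet genes 3 rose and 1 fell adjusted over the list alone, at a median of 0.03 (camera adjusted p = 0.229). Of 15 spermatogonial genes 1 rose and 4 fell in the same way, at a median of -0.06 (camera adjusted p = 0.421), and of 19 immediate-early genes 3 fell, at a median of -0.18 (camera adjusted p = 0.295). Sertoli cell genes lay lower at day 60 by a median of -0.18, with 2 of 23 fallen adjusted over the list alone (camera adjusted p = 0.0587). In wild-type-labelled arrays over the same interval, of these lists only the cholesterol list had a member past the threshold adjusted over the list alone (1 fell), and whether the labels differ in this change was not tested for these lists. No slide held knockout-labelled arrays of both day 40 and day 60, so slide and age are mixed in the knockout-labelled shifts. With slide as a fixed block 0 probes passed by limma there, and 1198 had an unadjusted p under 0.05.

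Among the cell types not yet described, spermatogonial genes had median differences between labels of 0.16 at day 40 (camera adjusted p = 0.271) and 0.12 at day 60 (adjusted p = 0.291), and macrophage genes of 0.12 at day 40 (adjusted p = 0.421). Red blood cell genes, of which 5 were measured, had medians of 0.60 at day 40 (adjusted p = 0.410) and -0.51 at day 60 (adjusted p = 0.575). Of 10 epididymis markers 2 rose at day 21 adjusted over the list alone, at a median of 0.01 and a mean of 0.52 (camera adjusted p = 0.659). The mean of this list at day 21 ran from -5.12 to -3.66 in knockout-labelled and from -5.09 to -4.74 in wild-type-labelled arrays. The adipocyte list had a mean of -2.47 in day 21 knockout-labelled replicate 2, against -0.35 and -0.76 in the other arrays of that group.

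Alleles linked to Plin1, which a knockout moved between strains can carry along, were not seen as an excess of differing genes near it. At an unadjusted p under 0.05 in the average over ages, 8 of 99 genes within 10 Mb and 1483 of 16975 elsewhere differed, an odds ratio of 0.918 (one-sided Fisher exact p = 0.643). Of the 3 other called genes 0 lay near, which was nearly certain with so few calls and decides nothing.

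For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For the comparisons of labels the number of splits with as many called probes, the real one included, was 1 at day 21 (488 called, highest other 4), 1 at day 40 (1 called, highest other 0) and 1 at day 60 (1 called, highest other 0). It was 1 from day 21 to day 40 in wild-type-labelled arrays (20905, highest other 0), 10 from day 40 to day 60 (0 by limma, with an unadjusted p under 0.05 for 4184, highest other 1), 1 from day 21 to day 40 in knockout-labelled arrays (17617, highest other 190) and 1 from day 40 to day 60 (1, highest other 0). For called gene lists it was 10 at day 21 (2 lists, highest other 13), 8 at day 40 (3 lists, highest other 10) and 10 at day 60 (1 list, highest other 7). For the average over ages, 5 of 100 splits called at least the real 6 probes, with a highest other of 286, and 96 of 100 called at least the real 2 lists, with a highest other of 12. For the interaction, 9 of 100 splits called at least the real 9 probes, with a highest other of 97. Chance can therefore not be excluded for the number of called probes or lists in the average over ages and the number of interaction calls. These counts do not bear on the size of a single gene's difference, such as that of Plin1. Splits that call several times the real count point to a structure of the arrays, whose source was not tested. At the single ages too, most splits called at least as many lists as the real one, so the number of called lists does not set the labels apart there.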
